A study of Drosophila melanogaster with 8 samples.

How the data were processed

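Poly(A) RNA of Drosophila melanogaster heads was sequenced from flies of 3 and 10 days after eclosion, kept on standard food or on food with 5 mM spermidine, a polyamine. Per the labels, heads were broken off frozen flies by vortexing, poly(A) RNA was selected from total RNA, and adaptor-ligated cDNA was size selected and amplified by PCR before sequencing on an Illumina instrument. Nothing in the labels marks the strand of a read. There were 4 groups of 2 libraries, 8 in all. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The day 3 and day 10 libraries were registered in separate blocks of entries, and no label gives a batch that holds both ages.

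The authors deposited 1 file of aligned reads per library, with 1 line per read giving the sequence, start, end, name, score and strand. The submitters' processing notes name CASAVA and the dm3 build; aligner settings and the treatment of reads with several positions are not given in the sources used here. In 7 libraries every deposited interval was 35 bases long and the name and the score were 0. In the normal-food day 3 replicate 2 library the intervals were 38 to 47 bases long, 42 bases in 99.9% of reads, with read names and an alignment score in the authors' deposited file; 0 read names occurred more than once. Libraries held 20924901 to 25488639 reads, except 43868480 in that library. Distinct positions numbered 4789375 to 9495552 per library, 20.5% to 26.8% of the reads, and without molecular identifiers repeated positions cannot be divided into PCR copies and separate molecules.

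The annotation at hand belongs to a later build than dm3. Coordinates were not converted between builds, and no gene names, exons or gene lists were used. The gene lists and the single genes named in the design were therefore not analysed here, and neither were counts over exons or gene bodies, nor checks of GC content and gene length. Reads were counted by their middle base in fixed windows of 1000 bases along dm3, which the design had named for this case. Positions are given from 1.

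A deposited line is the position of a read, not a count per gene or window. The design had named edgeR's quasi-likelihood test for files that list reads, but it was not used: no deposited column holds counts, and the test was limma-trend instead. This departs from the design as written. Windows with at least 10 reads in at least 2 libraries were tested, 54819 of the 106867 with a read; they held 99.55% to 99.78% of the reads. Counts were scaled by library total and a trimmed mean of M values (30% of M and 5% of A trimmed, written in R) and taken as log2(CPM + 0.5). One linear model of 4 group means was fitted to the 8 libraries with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust empirical Bayes (statmod 1.5.0), and p-values were adjusted by the Benjamini-Hochberg method over the windows tested, at 5%. Fold changes on the log2(CPM + 0.5) scale understate the change of low windows. Neighbouring windows share transcripts, so counts of windows are not counts of genes; windows called in 1 direction with at most 1 window between them were merged into regions.

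Comparisons were spermidine against normal food at each age, day 10 against day 3 on each food, the difference between the spermidine responses at both ages (the interaction), and both main effects. Named windows were, per comparison, the 8 largest rises and 8 largest falls among windows past 5%, with a mean of at least 5 CPM over the 8 libraries and no overlap between the libraries compared. The condition on overlap was not applied to the interaction, which does not set 2 groups against each other. The naming rule, the comparisons and most of the alternatives were written before the data were examined. Windows of the most reads, longest runs of windows and sets of windows were described by rules chosen afterwards, and shares of reads per sequence were compared with exact 2-sided permutation tests of 4 against 4 libraries (scipy 1.17.1), whose smallest p is 0.0286, with Benjamini-Hochberg adjustment over 16 sequences or groups of sequences. With 2 libraries against 2 the smallest exact p is 0.333, so no such test was run within an age. The permutations did not keep the other factor fixed: libraries were exchanged across ages in the food test and across foods in the age test. Exchange only within an age, combined over both ages, was not run. It allows fewer divisions, and its smallest p would lie above 5%.

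The fit was tested on simulated data, with counts drawn for the real windows and 200 of them changed, up or down at random. The changed windows were drawn only among those above a minimum mean level. Each window was given the median spread of windows of like level. Recovery in lower windows and in windows of wider spread was therefore not measured. Far more windows were called with spermidine in the data, unequally in the 2 directions. The rates below do not describe the fit, or its scaling, under such a change. For spermidine at day 3, 92.0% of 4-fold and 18.5% of 2-fold changes were recovered among 51914 and 51848 windows. For spermidine at day 10 these shares were 91.5% and 20.0% among 51851 and 51861 windows, and for age on normal food 96.5% and 14.0% among 51864 and 51828. For age on spermidine food they were 93.5% and 20.5% among 51815 and 51757 windows. For the interaction 70.5% of 4-fold changes were recovered among 51804 windows and 0.0% of 2-fold changes among 51795. For the mean spermidine effect the shares were 99.5% and 67.5% among 51859 and 51821 windows, and for the mean age effect 100.0% and 68.5% among 51780 and 51808. False calls exceeded 5% of the calls in several of these simulations, most in age on normal food with 2-fold changes (9.68% of 31 calls, 51828 windows) and spermidine at day 10 with 4-fold changes (8.04% of 199 calls, 51851 windows).

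Alternatives named beforehand were other scalings, limma-voom, other filters, a term for the replicate number, fits of only the groups compared, each position counted once, thinning to 20924901 reads, pseudocounts of 0.1 and 1, and leaving out each library. Alternatives added after the data were seen were windows of 5 kb, only the chromosome arms and chromosome 4, and a score of at least 100 in the library that has scores; for shares of reads, each position counted once, leaving out the 100 windows with most reads and leaving out each library.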

Results

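How transcript levels in the heads of Drosophila melanogaster respond to dietary spermidine, and to age, was examined at 3 and 10 days. Poly(A) RNA libraries were compared in 4 groups, on normal food or on food with 5 mM spermidine, with 2 libraries in each. Levels are CPM, read counts scaled to library size, in windows of 1000 bases of the dm3 build, as mean ± SD of 2 libraries. Depth was 22520723 and 43868480 reads in the normal-food day 3 libraries and 22560571 and 23691516 in the spermidine day 3 libraries. At day 10 it was 25488639 and 20924901 reads on normal food and 23406345 and 23398877 on spermidine.

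Food was the main axis of difference among the libraries. The first principal component held 63.8% of the variance and placed normal-food libraries between 94.0 and 123.5 and spermidine libraries between -148.7 and -48.7. The spermidine day 3 replicate 1 library lay nearest to the normal-food libraries. The second component, with 15.0% of the variance, placed day 3 libraries above day 10 libraries. Across windows, which are not independent, Pearson's r between the 2 libraries of a group was 0.953 on normal food at day 3, 0.973 on spermidine at day 3, 0.982 on normal food at day 10 and 0.978 on spermidine at day 10. Libraries of 1 food but different ages were about as close. Normal-food day 3 replicate 1 had a higher r with the normal-food day 10 libraries (0.9628 and 0.9655) than with its own replicate. For normal-food day 3 replicate 2 these values were lower (0.9232 and 0.9418). Between spermidine libraries of different ages r ran from 0.9416 to 0.9706. At an equal depth of 20924901 reads, 47070 to 49199 windows had at least 10 reads on normal food and 40644 to 43778 on spermidine. The 100 windows with most reads held 16.8% to 22.9% of the reads on normal food and 25.5% to 30.9% on spermidine.

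At day 3, transcript levels fell with spermidine in more windows than they rose, and falls over 4-fold were far more frequent than rises of that size. The window at 13024001 to 13025000 on chromosome 2R went from 94.0 ± 0.014 CPM on normal food to 2.06 ± 0.39 CPM on spermidine, a 45.7-fold fall (log2 change -5.22, SE 0.26; limma, Benjamini-Hochberg adjusted p = 3.76e-07). On the same arm, 19823001 to 19824000 went from 176 ± 73 to 3.20 ± 1.36 CPM, a 55.0-fold fall, and on 3R the window at 791001 to 792000 fell 51.6-fold, from 29.2 ± 7.7 to 0.57 ± 0.06 CPM. The 3 largest rises lay in unplaced sequence (Uextra). That at 24224001 to 24225000 went from 0.45 ± 0.56 to 23.1 ± 17.03 CPM. Its size is not fixed by these data, since the 2 normal-food libraries stood at 0.853 and 0.0567 CPM, 23 reads in all. Those at 17705001 and 28434001 missed the threshold without normal-food day 3 replicate 2 (limma, Benjamini-Hochberg adjusted p = 0.0775 and 0.0566), and the first of them also without spermidine day 3 replicate 2 (limma, Benjamini-Hochberg adjusted p = 0.08). Rises were smaller on the chromosome arms. On 2R, 4604001 to 4605000 rose 8.22-fold, from 9.23 ± 5.83 to 75.8 ± 34.4 CPM (14.9-fold without normal-food day 3 replicate 1), and on 3L 1195001 to 1196000 rose 6.20-fold, from 13.7 ± 3.4 to 84.8 ± 36.9 CPM. The longest run of falls covered 17 of 21 tested windows at 5124001 to 5145000 on 2L (median log2 change -1.83), followed by 15 of 16 windows at 773001 to 789000 on chromosome 4 (median -2.51).

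In all, 9115 of 54819 windows passed 5% at day 3, 2370 higher and 6745 lower, in 1944 and 4508 merged regions. Of these, 59 were over 4-fold higher and 1617 over 4-fold lower. The libraries of the foods did not overlap in 59.2% of the windows tested, against 33.3% by chance with 2 libraries each. Scaled by library totals alone, 902 windows were higher and 9136 lower, and the median log2 change of all windows was -0.21 in place of -0.0061. Among the 23585 windows with a mean of at least 5 CPM, 1826 were higher and 2742 lower, with a median log2 change of 0.18. A separate fit of 23759 windows of that level, with its own scaling and variance trend, gave 889 higher and 3249 lower, with a median of 0.02. Over all windows the count was 2755 without spermidine day 3 replicate 2 (213 higher, 2542 lower) and 5724 without normal-food day 3 replicate 2 (911 higher, 4813 lower).

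At day 10 falls were again deeper than rises and more numerous over all windows. On chromosome 4, the window at 1052001 to 1053000 went from 273 ± 115 CPM on normal food to 2.27 ± 0.66 CPM on spermidine, a 120-fold fall (log2 change -6.58, SE 0.32; limma, Benjamini-Hochberg adjusted p = 8.31e-08). The window at 10401001 to 10402000 on 2R went from 215 ± 3 to 2.10 ± 0.016 CPM, a 102-fold fall, and that at 16654001 to 16655000 on 3L from 84.9 ± 1.1 to 0.65 ± 0.0027 CPM, a 130-fold fall. The largest rises were about 6-fold. On 3L, 4437001 to 4438000 rose 6.10-fold, from 18.9 ± 2.4 to 115 ± 42 CPM (log2 change 2.53, SE 0.33; limma, Benjamini-Hochberg adjusted p = 8.96e-05). On X, 7133001 to 7134000 rose 5.91-fold, from 2.64 ± 0.11 to 15.6 ± 3.8 CPM, and on 2L 16622001 to 16623000 rose 5.94-fold, from 5.45 ± 1.34 to 32.4 ± 8.3 CPM. The 3 longest runs of rises all lay on X, led by 16 of 18 tested windows at 20263001 to 20282000 (median log2 change 1.86) and 14 of 16 at 11004001 to 11020000 (median 1.48).

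In all, 19695 windows passed at day 10, 7678 higher and 12017 lower, in 4577 and 6877 merged regions. Over 4-fold changes numbered 60 higher and 3498 lower. The libraries of the foods did not overlap in 72.3% of the windows tested, against 33.3% by chance. With library totals alone 3918 were higher and 14695 lower, with a median log2 change of -0.28 in place of -0.066. Among the 23585 windows with a mean of at least 5 CPM, 6219 were higher and 4316 lower, with a median log2 change of 0.27. A separate fit of 23759 windows of that level, with its own scaling and variance trend, gave 3925 higher and 5845 lower, with a median of -0.04. Over all windows the count was 8066 without normal-food day 10 replicate 1 (1621 higher, 6445 lower), 13004 without normal-food day 10 replicate 2 (5242 higher, 7762 lower) and 10292 without spermidine day 10 replicate 1 (3115 higher, 7177 lower).

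Both ages gave the same direction in most windows, in comparisons that share no library. They do share 1 variance estimate per window from the common fit. Windows of small spread are therefore likelier to be called at both ages, and the overlap of independent lists is only a rough reference. Of the windows higher at day 3, 1471 were also higher at day 10, where independent lists would share 332, and 9 were lower. Of those lower at day 3, 5920 were lower at day 10, where independent lists would share 1480, and 0 were called higher by limma; 24958 windows had an unadjusted p under 0.05 at day 10, and 99.7% of the windows lower at day 3 had the same sign there. Pearson's r between the changes at both ages was 0.825 across all windows. Without normal-food day 3 replicate 2 it was 0.867, across all windows tested in both fits. With all libraries, r was 0.855 across the 23585 windows with a mean of at least 5 CPM. Windows are not independent replicates.

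**Figure D1:**
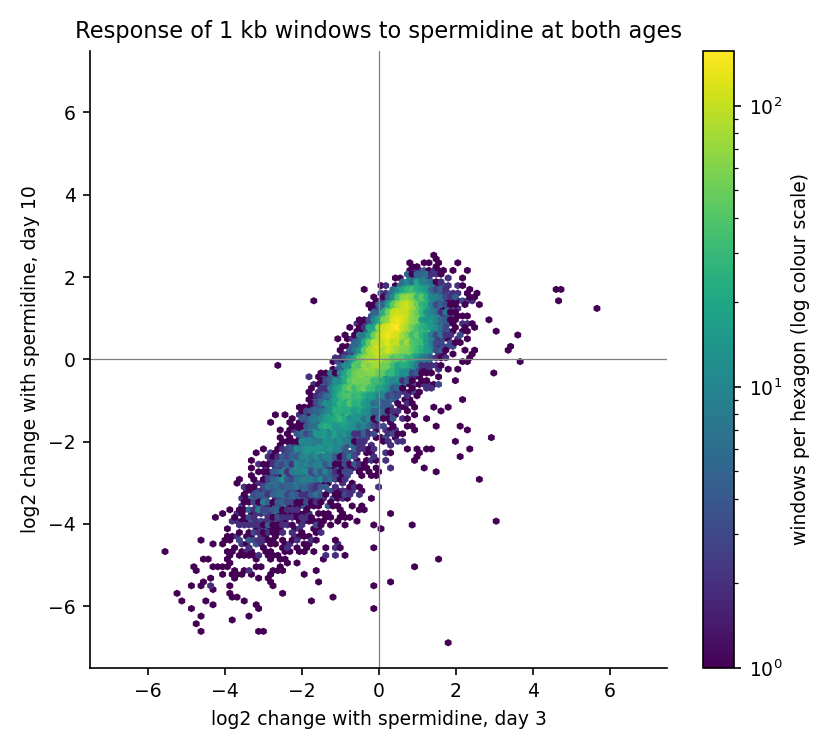
Each hexagon counts windows of 1000 bases with a mean of at least 5 CPM by their log2 change with spermidine at day 3 (horizontal axis) and at day 10 (vertical axis), on a log colour scale. At day 10 the cloud reaches further below 0 than above it; at day 3 a few windows rose nearly as far as others fell, and r across these 23585 windows was 0.855.

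Averaged over both ages, 24869 windows passed, 10315 higher and 14554 lower. With library totals alone these were 4944 and 18242, and the median log2 change of all windows was -0.23 in place of -0.020. Among the 23585 windows with a mean of at least 5 CPM, 7761 were higher and 5156 lower; the separate fit of 23759 windows of that level gave 5194 higher and 6811 lower. A set of 2445 windows, chosen as those over 4-fold lower in this comparison, held 7.10% ± 0.08 of all reads on normal food at day 3 and 1.17% ± 0.70 on spermidine (SD, n = 2). At day 10 the set held 9.07% ± 0.47 on normal food and 0.604% ± 0.18 on spermidine.

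The shares of reads on whole sequences also differed between the foods. Chromosome 4 took 0.605% ± 0.041 of reads on normal food and 0.252% ± 0.047 on spermidine (SD, n = 4), 2.40-fold lower, with all 4 spermidine libraries below all 4 normal-food libraries (exact 2-sided permutation p = 0.0286, the smallest possible, Benjamini-Hochberg adjusted p = 0.0457 over 16 tests). The heterochromatic scaffolds together took 0.152% ± 0.020 and 0.0646% ± 0.0086, 2.35-fold lower on spermidine, with the same exact permutation and adjusted p. Chromosome X took 20.0% ± 1.2 on normal food and 24.1% ± 1.3 on spermidine, higher in all 4 spermidine libraries than in any normal-food library, again with those exact p-values. With the same exact and adjusted p, 2L was lower on spermidine (15.45% against 16.69%), as were 2R (17.51% against 19.7%) and 3L (15.48% against 17.22%), while 3R did not pass (exact permutation p = 0.257). Shares of 1 library sum to a whole, so a gain on X lowers the shares of other arms. With each position counted once, chromosome 4 was 1.37-fold lower, the heterochromatic scaffolds 1.47-fold lower and X 2.01 points higher, with a Benjamini-Hochberg adjusted exact permutation p of 0.0381. Without the 100 windows with most reads, chromosome 4 was 2.23-fold lower, the scaffolds 2.18-fold lower and X 1.91 points higher; all 4 libraries of each food were still apart, with the exact permutation p still 0.0286, but the Benjamini-Hochberg adjusted p of 0.0508 missed 5% because 2R no longer had the smallest p (exact permutation p = 0.114). The 5 windows that contributed most made up 77.9% of the gain on X, at 9945001 to 9946000, 9947001 to 9949000 and 13653001 to 13655000, and 47.5% of the loss on chromosome 4, at 86001 to 88000 and 1052001 to 1055000. On the 3LHet scaffold the single window at 2398001 to 2399000 made up 93.0% of the loss. The typical window of chromosome 4 did not fall, with a median log2 change of 0.0131 averaged over both ages. Of its 766 tested windows, 25.5% were lower and 6.27% higher, against 28.6% and 17.9% on the large autosome arms. Median changes on the tested scaffolds ran from -0.664 (2LHet) to -0.0204 (3RHet).

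**Figure D2:**
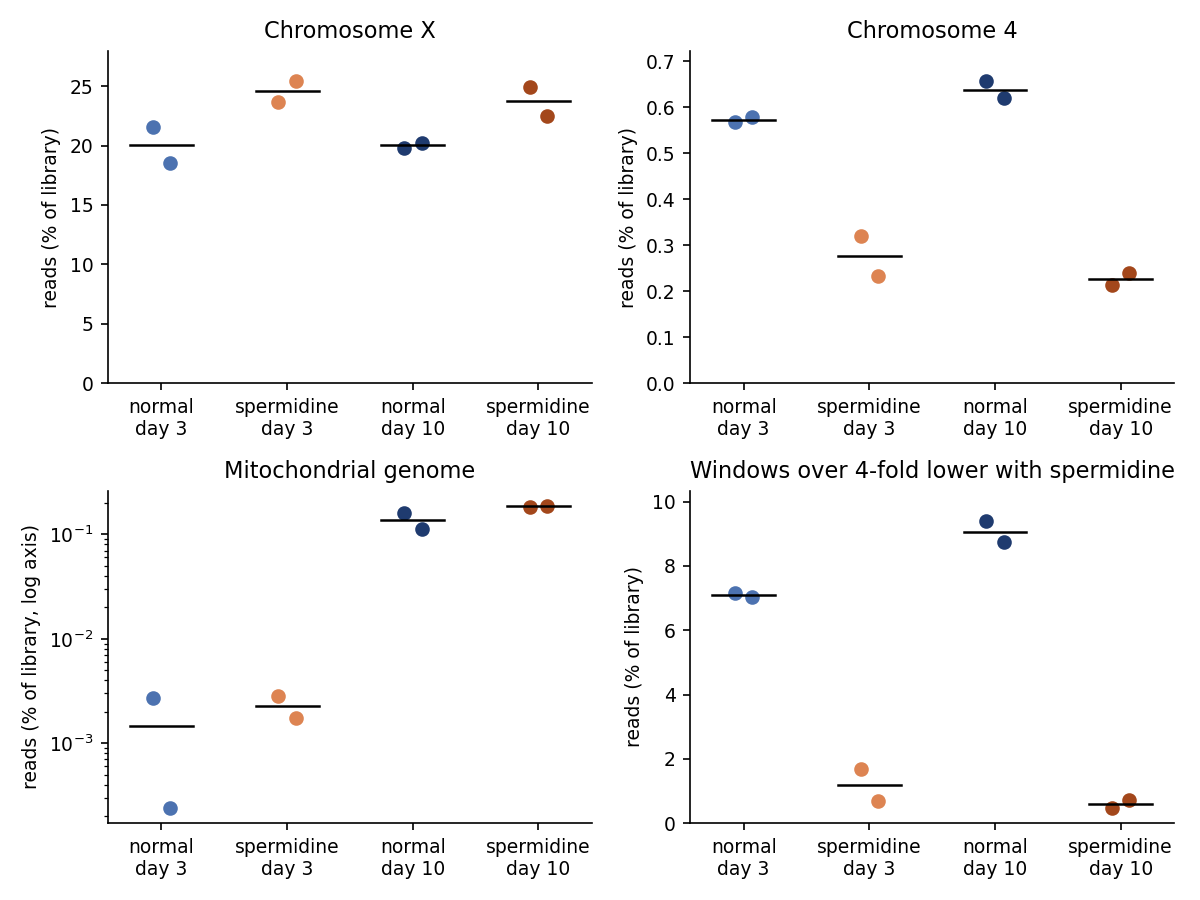
Points are single libraries and lines the mean of the 2 libraries of a group; axes give the percent of a library's reads on chromosome X, on chromosome 4, on the mitochondrial genome (log axis) and in the 2445 windows chosen as over 4-fold lower with spermidine. Chromosome 4 took 0.605% of reads on normal food and 0.252% on spermidine, as means of 4 libraries.

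With age, far fewer windows changed, and several of the deepest falls were neighbours. No labelled batch holds both ages, so a batch that coincides with age cannot be told apart from age in the age comparisons. On normal food, 2L 7744001 to 7745000 went from 404 ± 203 CPM at day 3 to 1.42 ± 0.17 CPM at day 10, a 285-fold fall, or 184-fold without normal-food day 3 replicate 1 (log2 change -7.63, SE 0.36; limma, Benjamini-Hochberg adjusted p = 1.67e-07). All 5 tested windows between 7740001 and 7753000 on 2L fell, with a median log2 change of -6.17. With a score of at least 100 in the library that has scores, the window at 7741001 missed the threshold on normal food and on spermidine food (limma, Benjamini-Hochberg adjusted p = 0.0823 and 0.063). On 2R, 4481001 to 4482000 went from 141 ± 44 to 0.65 ± 0.10 CPM, a 216-fold fall, and the next window fell 82.6-fold (43.9-fold without normal-food day 3 replicate 1). The longest run of falls covered 12 of 14 windows at 16774001 to 16788000 on 2L (median log2 change -2.27). Among rises, 2R 14271001 to 14272000 went from 14.0 ± 10.4 to 747 ± 95 CPM, a 53.3-fold rise (34.9-fold and 113-fold without normal-food day 3 replicates 1 and 2), and 13 of the 14 mitochondrial windows tested rose.

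In all, 1108 windows changed with age on normal food, 542 higher and 566 lower. The count was 187 without normal-food day 10 replicate 1 (80 higher, 107 lower), 201 without replicate 2 of that group (75 higher, 126 lower) and 659 without normal-food day 3 replicate 2 (270 higher, 389 lower). Without normal-food day 3 replicate 1 it was 5427, and rises then outnumbered falls, 3587 to 1840.

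On spermidine food the same 2L and 2R positions fell with age. The window at 7744001 to 7745000 on 2L went from 849 ± 76 to 1.61 ± 0.77 CPM, a 526-fold fall, or 795-fold without spermidine day 10 replicate 1 (log2 change -8.70, SE 0.36; limma, Benjamini-Hochberg adjusted p = 5.80e-08), and all 5 tested windows between 7740001 and 7753000 fell (median log2 change -7.08). That at 4481001 to 4482000 on 2R fell 104-fold, from 263 ± 28 to 2.52 ± 1.27 CPM (162-fold without spermidine day 10 replicate 1). On X, 361001 to 362000 rose 50.7-fold, from 0.75 ± 0.06 to 38.3 ± 20.5 CPM (31.4-fold without spermidine day 10 replicate 2). Runs of falls covered 7 of 8 tested windows at 1204001 to 1212000 on 3R (median log2 change -2.38) and also 7 of 8 at 15034001 to 15045000 on X (median -2.08).

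In all, 732 windows changed with age on spermidine food, 223 higher and 509 lower. Of these, 127 were higher and 265 lower in both foods, where independent lists would share 2.20 and 5.26. The age comparisons of the 2 foods share no library. They do share 1 variance estimate per window, and a batch that coincides with age would act on both. Of the windows higher with age on normal food, 74.4% had the same sign on spermidine food and 2 were called lower; of the lower ones, 98.8% had the same sign. Pearson's r between the age changes on the 2 foods was 0.369 across windows, which are not independent replicates. The count was 343 without spermidine day 3 replicate 1, 429 without spermidine day 10 replicate 1, 455 and 456 without either normal-food day 10 library (replicates 1 and 2), and 1194 and 1142 without either normal-food day 3 library. Averaged over both foods, 2163 windows changed, 865 higher and 1298 lower. That count was 858 and 942 without normal-food day 10 replicates 1 and 2, 1323 without spermidine day 3 replicate 1, 1440 without spermidine day 10 replicate 1 and 4752 without normal-food day 3 replicate 1, where rises outnumbered falls, 2660 to 2092.

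Mitochondrial reads were far more frequent at day 10. They made up 0.00187% ± 0.0012 of reads at day 3 and 0.160% ± 0.034 at day 10 (SD, n = 4), an 85.7-fold ratio with all 4 day 10 libraries above all 4 day 3 libraries (exact 2-sided permutation p = 0.0286, Benjamini-Hochberg adjusted p = 0.457 over 16 tests, which does not pass). With each position counted once the shares were 0.00228% and 0.0289%, a 12.7-fold ratio. The window at 13001 to 14000 rose from 0.56 ± 0.71 to 189 ± 89 CPM on normal food (log2 change 7.58, SE 0.48; limma, Benjamini-Hochberg adjusted p = 2.53e-05), and from 0.57 ± 0.19 to 105 ± 25 CPM on spermidine food, 186-fold. No fold is given on normal food, where the 2 day 3 libraries stood at 1.07 and 0.0567 CPM, 28 reads in all. The window at 12001 to 13000 rose 87.8-fold on spermidine food. The 14th window, at 5001 to 6000, went from 3.53 to 91.0 CPM on normal food and from 5.77 to 315 CPM on spermidine food without passing 5% in either (limma, Benjamini-Hochberg adjusted p = 0.105 and 0.119). At 1001 to 2000, the normal-food rise missed the threshold without either normal-food day 10 library (limma, Benjamini-Hochberg adjusted p = 0.115 and 0.0936) and without either spermidine day 10 library (limma, Benjamini-Hochberg adjusted p = 0.0822 and 0.0803). On spermidine food it missed without any of the 4 spermidine libraries (limma, Benjamini-Hochberg adjusted p = 0.116, 0.0665, 0.301 and 0.191 without day 3 replicates 1 and 2 and day 10 replicates 1 and 2). At 2001 to 3000, the normal-food rise missed without either normal-food day 10 library (limma, Benjamini-Hochberg adjusted p = 0.0773 and 0.0817) and the spermidine-food rise without either spermidine day 10 library (limma, Benjamini-Hochberg adjusted p = 0.131 and 0.0965). Other alternatives ended calls at these windows as well, among them a pseudocount of 0.1 and a score of at least 100 (limma, Benjamini-Hochberg adjusted p = 0.0642 to 0.204).

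**Figure D3:**
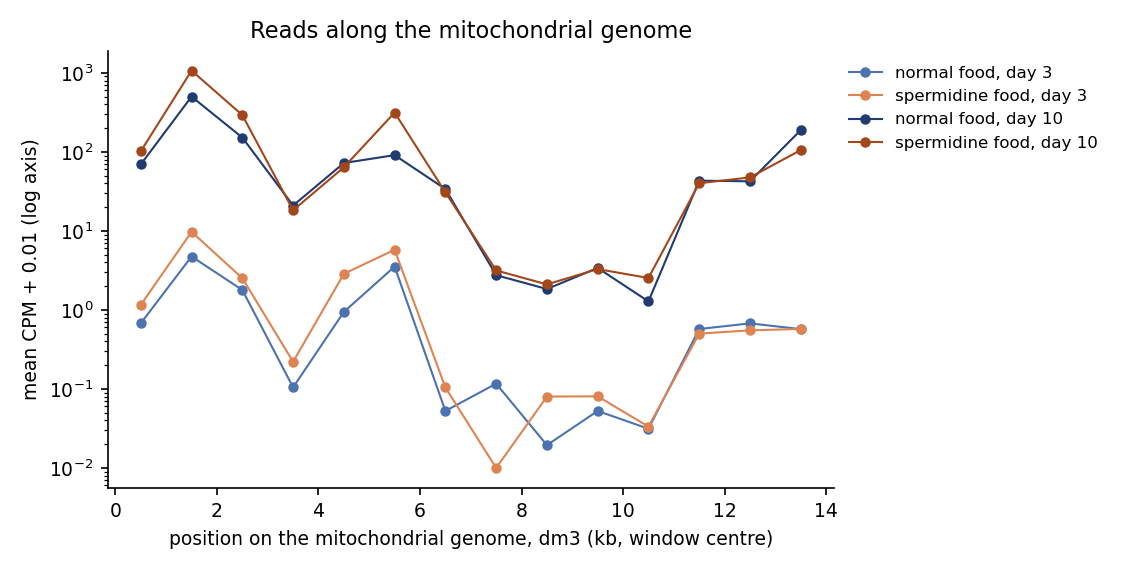
Mean CPM plus 0.01 (log axis) of the 2 libraries of each group in windows of 1000 bases along the mitochondrial genome of dm3 (kb). Both day 10 groups lie above both day 3 groups in all 14 windows, and the window at 1001 to 2000 was the highest in each of the 4 groups.

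The response to spermidine differed between the ages in 14 windows by limma. In all of them the log2 change with spermidine was more negative at day 10 than at day 3. At day 10 these windows fell with spermidine, by log2 -2.278 (X 19037001) to -6.093 (2R 14271001). At day 3 their log2 changes ran from -1.384 (2R 4033001) to 2.165 (3R 26042001). limma-voom called 5, all in the same direction, and 3848 windows had an unadjusted p under 0.05 by limma. Fits without 1 library also called windows whose log2 change with spermidine was higher (more positive) at day 10 than at day 3. These were 31 of 864 without normal-food day 3 replicate 1, 2 of 33 without normal-food day 3 replicate 2, 1 of 131 without spermidine day 3 replicate 2 and 8 of 42 without spermidine day 10 replicate 2. The clearest was 2R 10634001 to 10635000, at 22.3 ± 6.4 CPM on normal food and 68.8 ± 26.2 CPM on spermidine at day 3, and at 41.3 ± 14.3 and 0.90 ± 0.36 CPM at day 10 (interaction log2 -6.46, SE 0.50; limma, Benjamini-Hochberg adjusted p = 2.29e-04). At 2R 14271001 to 14272000 the level was 14.0 ± 10.4 and 11.3 ± 0.3 CPM at day 3 and 747 ± 95 and 10.4 ± 1.3 CPM at day 10. At 3R 26042001 to 26043000 it was 9.41 ± 1.49 and 46.5 ± 22.3 CPM at day 3 and 13.1 ± 5.1 and 2.06 ± 0.63 CPM at day 10. Without normal-food day 10 replicates 1 and 2, the window at 14271001 missed the threshold (limma, Benjamini-Hochberg adjusted p = 0.155 and 0.0879), as did that at 26042001 (limma, Benjamini-Hochberg adjusted p = 0.156 and 0.0689). Without spermidine day 3 replicate 1 the window at 14271001 missed it as well (limma, Benjamini-Hochberg adjusted p = 0.0584).

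The count of 14 depended on single libraries: it was 1 without either normal-food day 10 library, 5 without spermidine day 3 replicate 1, 8 without spermidine day 10 replicate 1, 33 without normal-food day 3 replicate 2, 42 without spermidine day 10 replicate 2, 131 without spermidine day 3 replicate 2 and 864 without normal-food day 3 replicate 1. With each position counted once 5 windows passed; the windows at 14271001 on 2R (log2 -1.32) and others then missed the threshold.

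**Figure D4:**
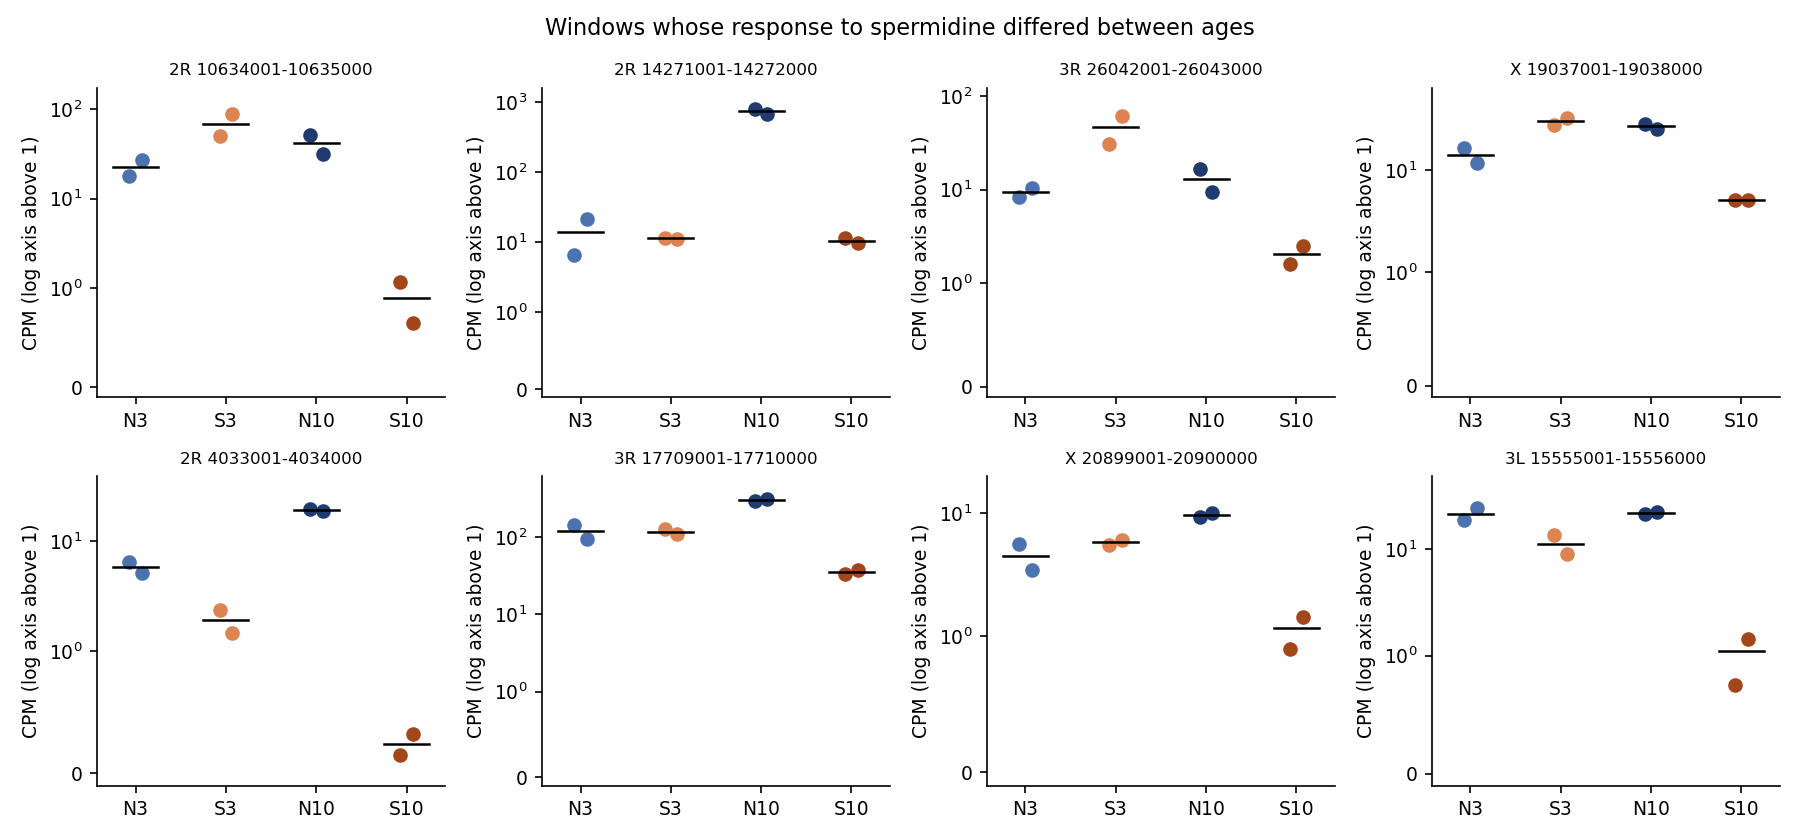
CPM (log axis above 1, linear below) in the 8 named windows whose response to spermidine differed between ages; points are libraries, lines the mean of 2, N3 and N10 normal food at day 3 and day 10, S3 and S10 spermidine food. In each panel the spermidine day 10 libraries lie below both normal-food day 10 libraries.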

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

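The 14 windows whose response to spermidine differed between day 3 and day 10 were singled out because the interaction itself passed the test (limma, Benjamini-Hochberg at 5%). The interaction test was planned, while some of the alternatives counted below (a score of at least 100 and only the chromosome arms and chromosome 4) were chosen after the data were seen. No technical explanation was weighed for single windows. The difference of the responses, day 10 minus day 3, was -6.46 (log2, SE 0.50) at 10634001 to 10635000 on 2R and -6.01 (SE 0.59) at 14271001 to 14272000 on 2R. It was -4.54 (SE 0.53) at 26042001 to 26043000 on 3R, -3.36 (SE 0.39) at 19037001 to 19038000 on X and -3.35 (SE 0.46) at 4033001 to 4034000 on 2R. It was -3.09 (SE 0.41) at 17709001 to 17710000 on 3R, -2.99 (SE 0.46) at 20899001 to 20900000 on X and -2.92 (SE 0.45) at 15555001 to 15556000 on 3L. Of these 8 windows, 7 lost the call under at least 1 alternative or left-out library, and that at 10634001 on 2R kept it in all that were run.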

How the results depend on the processing

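Window sizes of 5 kb, only the chromosome arms and chromosome 4, a score of at least 100 and all alternatives for shares of reads were chosen after the data were seen; the others were planned. Counts over gene bodies and gene list alternatives were not run for want of an annotation of the dm3 build used here, and reads at several places were not left out because 7 files give no read names and the other repeats 0. The 62 named windows gave 104 named changes, since some were named in several comparisons. Of 2112 values of these under alternatives, 2012 kept direction and call, 100 lost the call and 0 changed direction; the losses fell on 25 changes, in 21 windows. The cause of lost calls was not tested. Counting each position once limits a window to its number of positions and so compresses high windows. Thinning to the smallest library left 10 interaction calls. The interaction had the lowest recovery in simulation, with no 2-fold change recovered. A replicate left out leaves its group with a lone library, assumed to vary like the others.

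Requiring a mean of 5 CPM left 23759 windows and 4138 (spermidine, day 3), 9770 (spermidine, day 10), 282 (age, normal food), 223 (age, spermidine food), 3 (interaction), 12005 (mean spermidine effect) and 677 (mean age effect) calls. With 5 kb windows, 18283 were tested and 2927, 6464, 615, 8, 7963 and 1256 were called, in that order without age on spermidine food. In both settings fewer windows were tested. limma-voom called 466 for age on spermidine food and 5 for the interaction. The interaction gave 9 calls without a filter, 6 with a pseudocount of 0.1 and 5 with each position counted once, where age on normal food gave 703; the cause was not tested. The remaining alternatives gave 6541 to 10038 calls for spermidine at day 3, 16966 to 23813 at day 10, 787 to 1273 and 493 to 851 for age on normal and spermidine food, 10 to 16 for the interaction, and 22768 to 25362 and 1549 to 2225 for the mean effects.

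With the replicate number as a block, calls were 9170, 19612, 1125, 733, 10, 25108 and 2113, in the order of the comparisons above. Deviations of same-numbered libraries correlated between -0.368 and 0.27, so the numbers were not taken to pair the libraries. Leaving out 1 library gave 2755 to 12592 calls for spermidine at day 3, 8066 to 22467 at day 10, 187 to 5427 for age on normal food, 343 to 1194 on spermidine food, 1 to 864 for the interaction, 17833 to 25873 for the mean spermidine effect and 858 to 4752 for the mean age effect. Without the 100 windows with most reads, differences in shares were -0.419 points (chromosome 4), 1.91 (X) and -0.103 (heterochromatic scaffolds), with an exact permutation p still 0.0286 and a Benjamini-Hochberg adjusted p of 0.0508, which rose because 2R (exact permutation p = 0.114) left the sequences at the smallest p. With 1 library left out, differences in shares ranged from -0.377 to -0.337 points for chromosome 4, 3.61 to 4.65 for X, -0.0962 to -0.0800 for the heterochromatic scaffolds and 0.149 to 0.175 for mitochondrial reads. These left-out values carry no test, since 4 libraries against 3 cannot go below an exact p of 0.0571.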

Other observations

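The choice of windows described here, the regroupings and the tests of explanations were made after the results were seen. Several of the most abundant windows were higher with spermidine. The window with the most reads, 15712001 to 15713000 on 3R, stood at 19340 ± 3080 CPM on normal food and 31140 ± 460 CPM on spermidine at day 3, and at 28760 ± 4470 and 55880 ± 2510 CPM at day 10; averaged over both ages it was higher with spermidine (log2 0.83, SE 0.27; limma, Benjamini-Hochberg adjusted p = 0.0229). At neither age alone did it pass (limma, Benjamini-Hochberg adjusted p = 0.222 at day 3 and 0.064 at day 10). On X, 9948001 to 9949000 was higher at both ages, with 6227 ± 1760 and 15620 ± 3660 CPM at day 3 and 5865 ± 1260 and 15710 ± 4850 CPM at day 10. By contrast, 8641001 to 8642000 on 3L stood at 4544 ± 584 and 4190 ± 73 CPM at day 3 and did not pass the test at either age, and 9949001 to 9950000 on X did not pass averaged over both ages (limma, Benjamini-Hochberg adjusted p = 0.239).

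The 8 libraries were regrouped, in a model without the interaction, to see whether other divisions gave as many windows for either main effect. With age kept in the model, the real division by food was the 1 among 34 divisions of 4 and 4 that gave as many windows, with 24045 windows against 1 in the highest other division. With food kept in the model, the real division by age was likewise 1 of 34, with 1804 windows against 55 in the highest other. The other divisions leave the real difference of food or age in the spread, which by itself leaves few windows to call. The real divisions thus ranked first, but the gap in counts does not measure chance. If the 2 libraries of a group share their flies, most of these divisions part libraries that are not independent, and chance differences between groups of flies are then not excluded.

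Windows lower with spermidine were less frequent on X. Averaged over both ages, 18.8% of tested X windows were lower, against 28.6% on the large autosome arms, and 23.9% were higher, against 17.9%. To allow for neighbouring windows that move together, the calls were shifted in a circle along the arms 10000 times. Shifts put 2794 ± 327 lower calls on X where 1968 were observed (permutation p = 0.007, Benjamini-Hochberg adjusted p = 0.00933 over 8 tests), which argues against an even spread over the arms. The biology behind it was not tested.

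The deep falls with spermidine may have technical sources. Only the sources named below were weighed. The sample labels used gave food, age and replicate but not the sex of the flies, and a difference in sex between libraries was not examined. A few abundant windows taking the reads cannot account for them: windows over 4-fold lower at 1 age had a median log2 change of -1.87 or lower at the other age under each of 3 scalings, while scalings moved the median of all windows by 0.246 or less. Duplicated reads cannot either, since the median of 2443 of the 2445 windows over 4-fold lower, those testable with each position counted once, was then -2.10. RNA of another source carried by the heads in differing amounts cannot be told apart from a response to spermidine of unequal strength: between the 2 spermidine day 3 libraries these windows shifted together by 0.639 (log2, relative to windows of like level), but windows over 2-fold higher with spermidine shifted the opposite way by -0.263. In the other groups the lower windows shifted by 0.0804 (normal food, day 3), 0.105 (normal food, day 10) and -0.208 (spermidine, day 10), and the higher windows by -0.302 on normal food at day 10, so such a shift also arises without spermidine. The response to the food itself, the biological explanation in the design, stays open.

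Mitochondrial reads at day 10 exceeded those at day 3 by 85.73-fold, or 12.68-fold with each position counted once. Of the 14 windows with 10 or more reads in each day 10 library, 0 lacked a day 3 read. None was thus wholly missing from the day 3 files. Removal of most of their reads is not excluded, because 1 read in 1 library was enough to pass. The mitochondrial genome held 105 to 633 reads per day 3 library and 23481 to 43950 per day 10 library. Whether such reads were also removed from the day 10 files was not tested, so the ratio may compare what removal left. The window at 10001 to 11000 held 1 read in each replicate 1 library at day 3 and 0 in each replicate 2 library. A preparation or processing batch that coincides with age cannot be told apart from age itself, since no labelled batch holds both ages. Age stays open as an explanation, untested.

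At day 3, 100 of 480 tested windows of unplaced sequence were higher with spermidine, against 2370 of all 54819 windows. Most lay on Uextra, where 92 of 374 were higher and 5 lower. On U, 8 of 106 were higher and 14 lower. At day 10 lower windows outnumbered higher ones, 55 to 14 on Uextra and 26 to 3 on U. Longer reads or other alignment of the normal-food day 3 replicate 2 library cannot be told apart from a response to spermidine. Over 444 unplaced windows, whatever their change, the median log2 change was 0.66 with that library and 0.353 without it, when only 1 normal-food library of that age is left. Between the normal-food day 3 libraries, unplaced windows stood 0.44 higher (log2) in replicate 1 than in replicate 2, against 0.01 in other windows. The share of reads on U was 0.302% ± 0.270 on normal food and 0.666% ± 0.030 on spermidine at day 3 (SD, n = 2).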
